A study of Danio rerio with 45 samples.

How the data were processed

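Bulk RNA-seq was made by the authors from zebrafish (AB) animal-pole blastula explants. Per the labels, ndr2 mRNA was injected into 1 cell at the 128-cell stage at 2, 6 or 10 pg, controls were uninjected, and one condition received 10 pg with CHX at 50 µg/µl from 20 min after injection. Explants were sampled at 4, 5 and 6 hpf, giving 15 groups of 3 libraries from TRIzol-extracted total RNA. Groups were taken from the sample titles. The sample descriptions carry other figures in place of the doses, and the titles were followed.

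The deposited table holds raw counts per Ensembl gene, and per the labels the authors used STAR, featureCounts and DESeq2 with the GRCz11 build, without versions or settings. Annotation release and strand setting are not given in the sources used here. The table has 31465 genes and 45 columns. Totals per library ran from 12137856 to 28551066 counts, with a median of 20959131. At these totals a level of 1 CPM rests on few counts in a library, so lower levels are imprecise. Symbols were matched for 28965 genes, and 1.25% of counts fell in genes without one.

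The columns of replicate 3 of 10 pg and replicate 3 of 10 pg with CHX at 4 hpf were equal in all genes (20553891 counts, 23091 genes with a count). The highest share of equal counts in any other pair was 24.61%. The values do not say which group the column belongs to, so both were left out, a departure from the fixed design that was made after the data were examined. The fit therefore used 43 libraries, and the fit of all 45 columns as designed and the column in 1 group alone were tried as alternatives.

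Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood, 1 coefficient per group, 28 residual degrees of freedom, common dispersion 0.128). Genes passed filterByExpr at a minimum count of 10 and total of 15, leaving 21075 of them. p-values were adjusted by Benjamini and Hochberg within each of 21 comparisons, with a threshold of 0.05. These were each dose and CHX against the control of its age, 10 pg against 2 pg, CHX against 10 pg, successive ages of the controls, and the 10 pg effect at 6 hpf against that at 4 hpf. DESeq2 1.42.0 was run on the same groups. Other alternatives were RLE scaling, library totals only, no count filter (29460 genes), a replicate block, libraries of the same age only and leaving out 1 library. Those chosen after the data were examined were the age position as a covariate, a replicate block within each age, the assignments of the shared column, leaving out the 2 pg and 6 pg libraries of 4 hpf, and library totals for results without CHX.

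Gene lists (20, with 445 entries, of which 371 matched a gene) were written before the data were examined: Nodal ligands and antagonists, Nodal receptors and transducers, endoderm, prechordal plate, notochord and axial mesoderm, ventrolateral and paraxial mesoderm, Fgf, Wnt, Bmp, epidermal and neural ectoderm, enveloping layer, yolk syncytial layer, primordial germ cells, maternally loaded, early zygotic, cell movement and adhesion, immediate early, p53 and stress, and cell cycle. Of the matches, 38 were by base symbol, with at least 500 counts. Lists were tested with camera in limma 3.58.1 (correlation 0.01, log CPM with prior count 2, at least 5 members), adjusted over 420 tests, and again with the correlation estimated from the data.

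Genes were named by a rule fixed beforehand. It takes ndr2 in all groups, the 8 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and separated libraries, up to 4 called members of each list, and 10 marker genes in the dose comparisons. For genes higher in both treatments it takes the 8 with the largest smaller change. Not each gene the rule allows is printed. Where a group held 0 counts the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts the ratio of sums is given with a counting interval.

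The tests were tested on simulated data with 200 planted genes. With 10 pg against control at 6 hpf, 26% of planted 2-fold, 68% of 4-fold, 88% of 8-fold and 100% of 16-fold changes were recovered with 7 false calls. At 4 hpf, with 2 libraries against 3, the shares were 18%, 70%, 86% and 92% with 1 false call. A planted 2-fold change of the cell cycle list was called and 0 of 19 other lists were. Genes were drawn independently, so the effect of correlation between genes on the list tests was not tested. Planted genes were taken from those well counted in controls, so recovery of genes with few counts there was not tested either. Overlaps were compared with 1 data set per age simulated without an effect on the same shared controls. It gave 0 genes called higher in any comparison, so its lists were also cut at the observed lengths by p-value, a step chosen after the results were seen.

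Replicate numbers come from the titles, and whether they pair libraries was checked by correlating each library's deviation from its group mean over 10851 genes. All 3 same-number correlations exceeded 0.1 in 4 of 20 comparisons, 10 pg against control at 6 hpf, CHX against control at 5 and 6 hpf, and CHX against 10 pg at 5 hpf. CHX against 10 pg at 4 hpf has 2 such pairs and fell outside this rule, with 0.82 for both and -0.82 for the other pairs. With 2 libraries a group's deviations mirror each other, so these are 1 value, and the libraries may pair there too. An age position was computed for each library over 12425 genes that changed more than 2-fold between controls at 4 and 6 hpf. Figures were drawn with matplotlib 3.10.9. Injection day, clutch and sequencing batch are not given in the sources used here and were not modelled.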

Results

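The series held 45 RNA-seq libraries of zebrafish (AB strain) blastula explants in 15 groups of 3. The explants carried 0, 2, 6 or 10 pg of ndr2 mRNA, or 10 pg with cycloheximide (CHX, which blocks translation), and each condition was sampled at 4, 5 and 6 hours post fertilization (hpf). ndr2 encodes a Nodal ligand, a secreted TGF-beta family signal that specifies mesoderm and endoderm. CHX without ndr2 was not analysed here, so the CHX groups carry both treatments. Library totals ran from 12137856 to 28551066 counts. Replicate 3 of the 10 pg group and replicate 3 of the 10 pg with CHX group at 4 hpf were the same column, equal in all 31465 genes. Both were left out, a change from the design, which leaves 43 libraries and n = 2 in those 2 groups (n = 3 elsewhere). Genes were tested with edgeR quasi-likelihood tests, and adjusted p is the Benjamini-Hochberg value over 21075 genes in each of 21 comparisons. A gene is said to rise or fall where that value was below 0.05. Errors are standard errors for log2 fold changes and standard deviations for levels in CPM (counts scaled to library size). The p-values measure only the spread between these samples, which may be technical. Comparisons, groups, lists and naming rule were set before the data were examined. Symbols are those of the reference, some of which are in capitals.

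ndr2 itself followed the amount given at 4 hpf. It stood at 0.494 ± 0.176 CPM in controls, 6.91 ± 0.125 with 2 pg, 41.6 ± 8.52 with 6 pg and 128 ± 19.9 with 10 pg (n = 2), and at 192 ± 154 with CHX (n = 2). Against the control the log2 rises were 3.81 ± 0.55 (adjusted p = 6.37e-06), 6.40 ± 0.59 (adjusted p = 1.17e-08), 8.03 ± 0.64 (adjusted p = 5.97e-10) and 8.61 ± 0.65 (adjusted p = 1.42e-10). At 5 hpf the levels were 0.657 ± 0.321 CPM in controls, 2.62 ± 0.859 with 2 pg, 10.7 ± 6.64 with 6 pg, 16 ± 4.31 with 10 pg and 59.5 ± 38.6 with CHX. The 2 pg group was not called against the control there (adjusted p = 0.821). At 6 hpf ndr2 stood at 0.454 ± 0.14 CPM in controls, 6.53 ± 2.31 with 2 pg, 22.0 ± 8.25 with 6 pg, 21.5 ± 6.04 with 10 pg and 21.3 ± 5.76 with CHX. With CHX, ndr2 was higher than with 10 pg alone at 5 hpf by 1.89 ± 0.46 log2 units (adjusted p = 0.000903), and was not called different at 4 hpf (adjusted p = 0.828) or 6 hpf (adjusted p = 0.981). The counts do not tell injected from endogenous transcript.

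**Figure D1:**
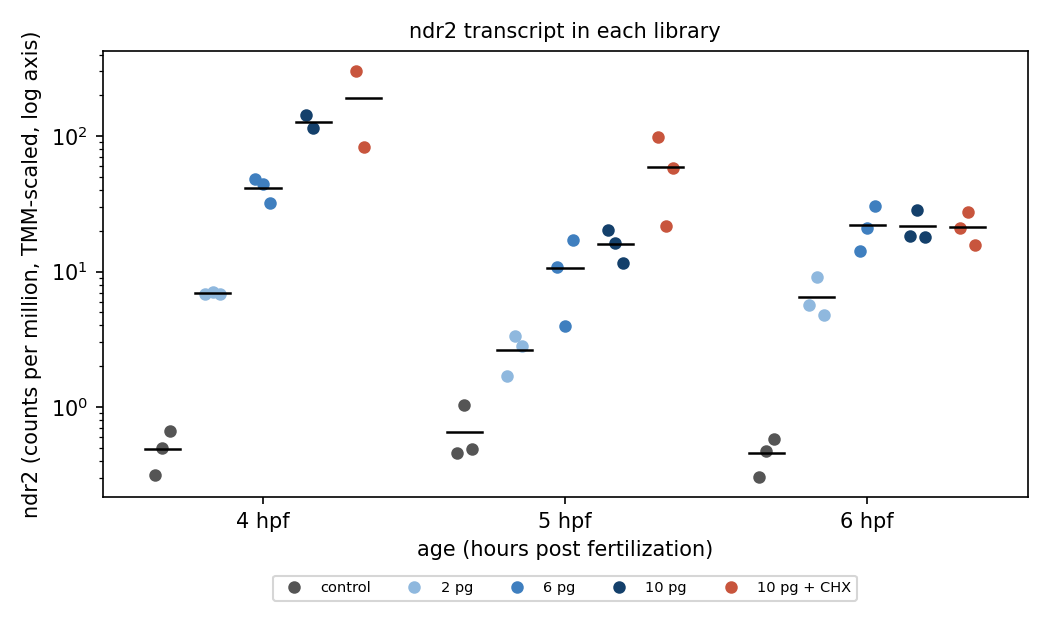
ndr2 transcript in CPM (log axis) in each of the 43 libraries used, by age and amount injected, with group means as bars. At 4 hpf the group means climb from 0.494 in controls to 128 with 10 pg, while at 6 hpf the 6 pg, 10 pg and CHX groups stand near 22.0, 21.5 and 21.3.

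At 4 hpf (n = 2 against 3), the Fgf ligand gene FGF4 rose with 10 pg by 7.61 ± 1.2 log2 units (adjusted p = 0.000641), and the forkhead factor FOXC1 by 7.58 ± 1.00 (adjusted p = 3.45e-05). The endoderm and axial forkhead genes FOXA2 and foxa3 rose by 6.80 ± 0.94 and 5.96 ± 0.90, FGF3 by 6.53 ± 0.91, and CYP27C1, a retinoid-modifying enzyme, by 6.07 ± 1.00. The secreted Nodal inhibitors lft2 and lft1 rose by 5.65 ± 0.60 (adjusted p = 5.7e-07) and 5.61 ± 0.68 (adjusted p = 9.19e-06). The T-box factor tbxta rose by 4.90 ± 0.93, the notochord factor noto by 3.41 ± 0.70 and the mesendoderm homeobox gene mixl1 by 3.40 ± 0.70. GSC, the organizer gene goosecoid, rose by 3.04 ± 0.66 (adjusted p = 0.0468). VPS4A, a membrane-remodelling ATPase, fell by 1.60 ± 0.34 (adjusted p = 0.0277). In all, 29 genes rose and 2 fell (edgeR; 873 were higher and 919 lower at an unadjusted p below 0.05). DESeq2 called 70 higher and 16 lower, and without 10 pg replicate 1, where 1 library stands for the group, 250 rose and 335 fell. Without control replicate 2, 17 rose and 1 fell. With replicate numbers as a block within each age, chosen after the data were seen, 25 rose and 9 fell. Only 11 of the 29 genes stayed called higher there, so which genes are called depends on this setting more than the total does.

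Gene lists fixed beforehand were tested with camera, adjusted over 420 tests. Of 5 measured Nodal ligands and antagonists, 3 rose with 10 pg at 4 hpf (lft1, lft2 and ndr1) and 2 were not called (3 adjusted over the list alone, list adjusted p = 4.84e-11). Of 12 endoderm genes, 4 rose and 8 were not called, with sebox at 5.33 ± 0.95 (7 adjusted over the list alone, list adjusted p = 1.62e-11). Of 9 notochord and axial mesoderm genes, 3 rose and 6 were not called (5 adjusted over the list alone, list adjusted p = 1.51e-09). Of 11 prechordal plate genes, 3 rose, FOXA2, foxa3 and GSC, and 8 were not called (3 adjusted over the list alone, list adjusted p = 0.00104, against adjusted p = 0.206 with an estimated correlation). Its median log2 change was -0.02 where its mean was 1.2. Of 16 Fgf genes, 3 rose, FGF4, FGF3 and FGF8, and 13 were not called (5 higher and 1 lower adjusted over the list alone, list adjusted p = 1.58e-07, against adjusted p = 0.108 with an estimated correlation). FGF8 (ENSDARG00000003399) shares its symbol with a second gene, so the gene measured is fixed by this ID and not by the symbol. The 8 Nodal receptors and transducers were not called as a list (adjusted p = 0.784), with a median of -0.22 and a mean of 0.27, and 1 of them, mixl1, rose (2 adjusted over the list alone).

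With 10 pg at 4 hpf, the 24 enveloping layer, 16 epidermal and 16 yolk syncytial layer genes were higher as lists with 0 members called (adjusted p = 5.53e-06, 4.11e-05 and 0.0178, against adjusted p = 0.393, 0.338 and 0.0718 with an estimated correlation). The 23 early zygotic, 26 p53 and stress and 31 cell cycle genes were higher as lists with 0 members called (adjusted p = 2.57e-07, 0.00221 and 0.0112, against adjusted p = 0.245, 0.213 and 0.397 with an estimated correlation). The 21 ventrolateral and paraxial mesoderm, 20 Bmp and 26 cell movement genes were higher as lists with 0, 0 and 2 members called higher (adjusted p = 0.000357, 2.06e-05 and 1.96e-05, against adjusted p = 0.155, 0.151 and 0.189 with an estimated correlation).

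At 5 hpf, dkk1b, a secreted Wnt antagonist of the prechordal plate, rose from 3 counts over the controls, a ratio of 499 (95% counting interval 171 to 2420). Such intervals, and the floors given as at least a fold, cover counting error only. OSR1, a zinc finger factor of intermediate mesoderm and endoderm, rose by 7.23 ± 1.09 log2 units (adjusted p = 0.000221) and sebox by 6.98 ± 0.94 (adjusted p = 5.62e-05). lft2 went from 0.118 ± 0.133 to 14.5 ± 5.22 CPM (adjusted p = 2.58e-07) and tbxta from 2.07 ± 2.70 to 172 ± 57.6 CPM (adjusted p = 0.000254). FGF4 and FGF3 rose by 6.46 ± 1.06 and 6.30 ± 0.91, mixl1 by 5.34 ± 0.74 and the Bmp antagonist chrd by 3.50 ± 0.73 (adjusted p = 0.02). In all, 47 genes rose and 0 fell (edgeR; 391 were higher and 527 lower at an unadjusted p below 0.05), while DESeq2 called 65 higher and 5 lower. The count depends on single controls, with 61 higher and 26 lower without control replicate 3 and 30 and 0 without control replicate 2. With only the libraries of this age in the fit, 9 genes were called. Library totals as the only scaling moved the median change to 0.07 from -0.04.

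Among 12 endoderm genes, 6 rose at 5 hpf, with GATA5 at 5.39 ± 1.04 and foxa3 at 6.20 ± 0.88, and 6 were not called (7 higher and 1 lower adjusted over the list alone, list adjusted p = 2.94e-23). Of 11 prechordal plate genes, 5 rose, among them lhx1a, a LIM homeobox factor, at 4.36 ± 0.65, and 6 were not called (6 higher and 1 lower adjusted over the list alone, list adjusted p = 3.31e-17). Of 9 notochord genes, 4 rose, with FOXD3 at 3.38 ± 0.58, and 5 were not called (7 adjusted over the list alone, list adjusted p = 9.06e-28). Among 16 Fgf genes, 5 rose, with fgf24 at 5.56 ± 0.69 and FGF8 at 5.78 ± 0.79, and 11 were not called (12 adjusted over the list alone, list adjusted p = 2.77e-37). Of 14 Wnt genes, 2 rose, dkk1b and the noncanonical ligand wnt11f2 (3.35 ± 0.61), and 12 were not called (5 adjusted over the list alone, list adjusted p = 4.22e-12). Of 5 Nodal ligands and antagonists, 3 rose and 2 were not called (3 adjusted over the list alone, list adjusted p = 5.76e-20). Of 8 Nodal receptors and transducers, mixl1 rose and 7 were not called (2 adjusted over the list alone, list adjusted p = 0.000596). Outside the 8, the receptor gene ACVR1B (ENSDARG00000018968), unmatched because its symbol is shared, rose by 1.08 ± 0.16 (adjusted p = 0.000156). The 21 ventrolateral and paraxial mesoderm, 26 cell movement and 27 immediate early genes were higher as lists with 2, 2 and 0 members called higher (adjusted p = 4.69e-05, 3.45e-05 and 0.022, against adjusted p = 0.0954, 0.206 and 0.481 with an estimated correlation).

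At 6 hpf, mespab, a bHLH factor of presomitic mesoderm, rose with 10 pg from 1 count over the controls, a ratio of 734 (95% counting interval 131 to 29000). dkk1b went from 0.0687 ± 0.0777 to 30.2 ± 2.87 CPM (log2 8.69 ± 1.07, adjusted p = 3.67e-06). pcdh8, the paraxial protocadherin, rose by 8.13 ± 0.95 (adjusted p = 2.45e-06), and TBR1, a T-box factor, from 2 counts over the controls, a ratio of 252 (69.4 to 2090). tbxta reached 411 ± 115 CPM from 2.61 ± 2.64 (adjusted p = 2.52e-05) and GSC 90.4 ± 36.6 from 0.809 ± 0.681 (adjusted p = 2.2e-06). chrd reached 451 ± 186 CPM from 10.5 ± 2.44 (adjusted p = 9.93e-05). The endoderm regulator sox32 rose by 6.56 ± 1.17 (adjusted p = 0.00127), mixl1 by 6.09 ± 0.77, foxa3 by 7.29 ± 0.94 and FGF4 by 7.34 ± 1.19. In all, 100 genes rose and 0 fell (edgeR; 368 were higher and 208 lower at an unadjusted p below 0.05), while DESeq2 called 124 higher and 0 lower, and 64 rose and 0 fell without control replicate 2.

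Among the 5 Nodal ligands and antagonists, 4 rose at 6 hpf, with lft1 at 6.92 ± 0.77, lft2 at 7.01 ± 0.69 and spaw at 4.23 ± 1.00, and 1 was not called (4 adjusted over the list alone, list adjusted p = 1.36e-30). Of the 12 endoderm genes, 7 rose and 5 were not called (8 adjusted over the list alone, list adjusted p = 7.72e-40). Of 11 prechordal plate genes, 6 rose, with lhx1a at 6.87 ± 0.73, and 5 were not called (7 adjusted over the list alone, list adjusted p = 2.82e-37). Of 9 notochord genes, 5 rose and 4 were not called (7 adjusted over the list alone, list adjusted p = 3.02e-39). Of 16 Fgf genes, 8 rose and 8 were not called, with fgf17 at 3.59 ± 0.62 (13 adjusted over the list alone, list adjusted p = 5.43e-45). Of 14 Wnt genes, 5 rose and 9 were not called, with the antagonist frzb at 4.33 ± 0.94 and WNT5B at 3.40 ± 0.82 (6 adjusted over the list alone, list adjusted p = 3.98e-20). Of 21 ventrolateral and paraxial mesoderm genes, 5 rose and 16 were not called (6 adjusted over the list alone, list adjusted p = 1.17e-15). Of 26 cell movement and adhesion genes, 4 rose and 22 were not called, with the GTPase arl4ab at 3.69 ± 0.76 (7 adjusted over the list alone, list adjusted p = 7.18e-12).

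Of 8 Nodal receptors and transducers, mixl1 rose with 10 pg at 6 hpf and 7 were not called (2 adjusted over the list alone, list adjusted p = 5.14e-05). Outside the 8, the receptor gene ACVR1B (ENSDARG00000018968), unmatched because its symbol is shared, rose by 1.30 ± 0.16 (adjusted p = 4.06e-06). Of 20 Bmp ligands, antagonists and targets, 2 rose, chrd and admp (3.47 ± 0.57), and 18 were not called (2 adjusted over the list alone, list adjusted p = 0.177). NOG (ENSDARG00000058819), outside the 20 because its symbol is shared and its entry stayed unmatched, rose by 4.11 ± 0.565 (adjusted p = 1.82e-05). Of 27 immediate early genes, ier2a alone rose, at 3.69 ± 0.59 (3 adjusted over the list alone, list adjusted p = 0.00233, against adjusted p = 0.338 with an estimated correlation). Of 16 yolk syncytial layer genes, 2 rose, the endoderm factor GATA6 at 4.96 ± 0.83 and msgn1 at 2.72 ± 0.60 (2 adjusted over the list alone, list adjusted p = 0.0496, against adjusted p = 0.151 with an estimated correlation). None of the 16 neural ectoderm genes (list adjusted p = 0.0968), 16 epidermal genes (adjusted p = 0.174), 24 enveloping layer genes (adjusted p = 0.333) or 14 primordial germ cell genes (adjusted p = 0.58) was called. The same held for 20 maternally loaded transcripts (adjusted p = 0.659), 26 p53 and stress genes (adjusted p = 0.221) and 31 cell cycle genes (adjusted p = 0.641). The 16 neural genes leave out some genes with shared symbols, NOG among them. Of these, SIX3 (ENSDARG00000054879) rose by 6.135 ± 0.96 (adjusted p = 0.000183) and ZIC2 (ENSDARG00000015554) by 4.55 ± 0.71 (adjusted p = 0.000186). Of 23 early zygotic genes, FOXD3 alone rose, at 4.18 ± 0.59 (list adjusted p = 0.105).

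The effect of 10 pg differed between 6 and 4 hpf for 10 genes when the difference itself was tested. All 10 were lost without 10 pg replicate 2 at 4 hpf (0 called), and without replicate 1, 41 were larger and 2 smaller. For dkk1b the effect was 9.43 ± 1.55 log2 units larger at 6 hpf (adjusted p = 0.00389), for lhx1a 6.79 ± 0.97 (adjusted p = 0.000628) and for IRX3, an Iroquois homeobox gene, 6.65 ± 1.13 (adjusted p = 0.00527). TBR1 was called too (adjusted p = 0.00127), and no size is given because the controls at 6 hpf held 2 counts of it. SULF1, an extracellular sulfatase, differed by 4.33 ± 0.84 (adjusted p = 0.0237) and NRIP1, a nuclear receptor corepressor, by 4.28 ± 0.62 (adjusted p = 0.000628). The exchange factor genes arhgef37 and RASGEF1B differed by 2.34 ± 0.46 (adjusted p = 0.0237) and 2.22 ± 0.43 (adjusted p = 0.0236). TAGLN, an actin-binding protein of smooth muscle, had a smaller effect at 6 hpf, with a difference of -4.26 ± 0.79 (adjusted p = 0.0228), after a rise of 4.63 at 4 hpf (adjusted p = 8.51e-05). IRX3, RASGEF1B and TAGLN share their symbols with other genes, so the paralog is uncertain. Of 11 prechordal plate genes, 2 were larger at 6 hpf (5 adjusted over the list alone, list adjusted p = 9.6e-09), and of 14 Wnt genes, 1 was larger (5 adjusted over the list alone, list adjusted p = 8.63e-08). The Wnt gene was dkk1b, which is in both lists. As lists with 0 members called, the 24 enveloping layer, 16 epidermal and 23 early zygotic genes had a smaller effect at 6 hpf (adjusted p = 0.00148, 1.96e-05 and 0.00225, against adjusted p = 0.549, 0.319 and 0.5 with an estimated correlation). DESeq2 called 23 larger and 3 smaller. With replicate numbers as a block within each age, chosen after the data were seen, 16 were larger and 2 smaller. Library totals gave 5 larger and 1 smaller.

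**Figure D2:**
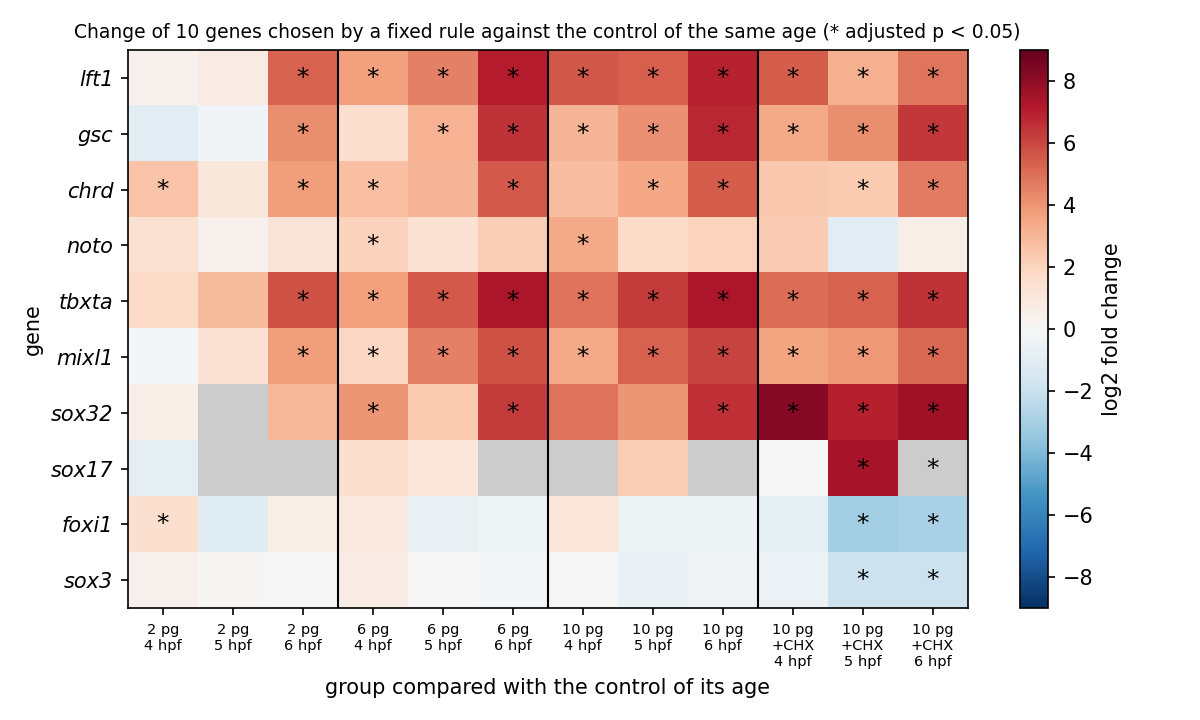
Log2 fold change of 10 genes chosen by the fixed rule (colour) in each injected group against the control of its age, with a star where adjusted p was below 0.05. Grey cells had 3 counts or fewer over a group, and lft1, tbxta and mixl1 were starred in every 6 hpf column.

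With 6 pg at 5 hpf OSR1 rose by 5.93 ± 1.06 log2 units (adjusted p = 0.00389), lft2 by 5.86 ± 0.69 (adjusted p = 1.18e-05) and tbxta by 5.49 ± 0.93 (adjusted p = 0.00191). FGF3, FGF8, sebox and foxa3 rose by 5.61 ± 0.89, 5.47 ± 0.78, 5.57 ± 0.90 and 5.57 ± 0.86, and dkk1b by a ratio of 105 (95% counting interval 35.5 to 511). Of 12 endoderm genes, 5 rose and 7 were not called (6 adjusted over the list alone, list adjusted p = 1.34e-15). Among 16 Fgf genes, 5 rose and 11 were not called (10 adjusted over the list alone, list adjusted p = 6.11e-28). Of the 5 Nodal ligands and antagonists, 3 rose and 2 were not called (3 adjusted over the list alone, list adjusted p = 1.34e-13). In all, 37 genes rose and 0 fell (edgeR; 468 were higher and 658 lower at an unadjusted p below 0.05), while DESeq2 called 56 higher and 5 lower, and 3 were called with only the libraries of this age in the fit. Without control replicate 1, or without control replicate 2, 19 rose and 0 fell. The 10 pg and 6 pg lists shared 34 higher genes, where independent lists would share 0.08. In data simulated without an effect on shared controls 0 genes were called higher, and lists cut there at the observed lengths shared 6. The groups share controls, so part of the excess may come from them, and 3 controls cannot be split.

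At 6 hpf, 6 pg raised mespab by a ratio of 813 (95% counting interval 145 to 32200), dkk1b by 8.11 ± 1.06 log2 units (adjusted p = 1.17e-05), pcdh8 by 7.92 ± 0.94 (adjusted p = 3.33e-06) and TBR1 by a ratio of 265 (73 to 2200). tbxta stood at 401 ± 166 CPM (log2 rise 7.27 ± 1.00, adjusted p = 2.6e-05), and foxa3 and lft1 rose by 7.30 ± 0.94 and 7.04 ± 0.77. xaf1, an apoptosis-linked gene, fell by 1.16 ± 0.28 and npm2a, a maternal histone chaperone, by 1.13 ± 0.25. Among 12 endoderm genes, 7 rose and 5 were not called (8 adjusted over the list alone, list adjusted p = 1.35e-24). Of 21 ventrolateral and paraxial mesoderm genes, 4 rose and 17 were not called (7 adjusted over the list alone, list adjusted p = 1.86e-08). In all, 107 genes rose and 27 fell, a higher share of 79.9%, which was 65.7% with library totals as the only scaling (median shift to -0.18 from -0.04). DESeq2 called 148 higher and 74 lower, a fit of only this age 245 and 44, and the age position defined below as a covariate 137 and 65. Without control replicate 3, 65 rose and 11 fell. The 10 pg and 6 pg lists shared 93 higher genes (0.51 for independent lists, 16 for simulated lists cut at the observed lengths), and part of this may come from the shared controls.

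With 2 pg, 1 gene was called at 5 hpf. fgf24, an Fgf ligand, went from 0.305 ± 0.125 to 5.05 ± 1.24 CPM (log2 4.04 ± 0.67, adjusted p = 0.0178), and the other 15 Fgf genes were not called (5 higher adjusted over the list alone, list adjusted p = 6.22e-12). By edgeR 423 were higher and 664 lower at an unadjusted p below 0.05, and DESeq2 called 11 higher and 3 lower. With all 45 columns as designed, and with only the libraries of this age, 0 genes were called. The call was also lost in 5 of the 6 fits that leave out 1 library of either group, all but the one without 2 pg replicate 2. The 9 notochord genes were higher as a list (adjusted p = 5.74e-09) with 0 called and 2 adjusted over the list alone. As lists, the 24 enveloping layer and 26 cell movement genes were higher with 0 members called (adjusted p = 7.48e-05 and 0.00729, against adjusted p = 0.468 and 0.444 with an estimated correlation). The 12 endoderm, 5 Nodal ligand and antagonist and 11 prechordal plate genes were higher as lists with 0 members called (adjusted p = 0.005, 0.0102 and 0.0496, against adjusted p = 0.365, 0.206 and 0.481 with an estimated correlation). With replicate numbers as a block in camera, the prechordal plate call was lost (adjusted p = 0.061). The 26 p53 and stress genes were lower as a list with 0 members called (adjusted p = 0.0437, against adjusted p = 0.447 with an estimated correlation).

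At 6 hpf, 2 pg raised pcdh8 by 6.27 ± 0.89 log2 units (adjusted p = 0.000241), foxa3 by 5.66 ± 0.88, lft1 by 5.33 ± 0.74 (adjusted p = 0.000166) and lft2 by 5.23 ± 0.67 (adjusted p = 4.31e-05). tbxta reached 139 ± 52.1 CPM (log2 rise 5.74 ± 0.94, adjusted p = 0.00102), FOXA2 rose by 5.16 ± 0.84, FGF8 by 4.74 ± 0.76 and P4HA2, a collagen prolyl hydroxylase, by 4.89 ± 0.66. CYP1B1, a cytochrome P450, fell by 4.55 ± 1.02 (adjusted p = 0.0193) and her11, a Hairy-related factor, by 2.36 ± 0.62. AADAT, an aminotransferase, fell by 2.02 ± 0.46 and the guanylate-binding gene gbp2 by 1.89 ± 0.49. Of 5 Nodal ligands and antagonists, 3 rose and 2 were not called (3 adjusted over the list alone, list adjusted p = 8.63e-08). Of 11 prechordal plate genes, 5 rose and 6 were not called (5 adjusted over the list alone, list adjusted p = 3.37e-10). Of the 12 endoderm genes, 4 rose and 8 were not called (7 adjusted over the list alone, list adjusted p = 1.43e-07, against adjusted p = 0.0622 with an estimated correlation). Higher as lists, with 0 members called, were the 24 enveloping layer and 16 epidermal genes (adjusted p = 0.0358 and 0.0226, against adjusted p = 0.708 and 0.595 with an estimated correlation). The 31 cell cycle genes were higher as a list with 0 members called higher and 1 lower (adjusted p = 0.0483, against adjusted p = 0.5 with an estimated correlation). In all, 81 genes rose and 181 fell, a higher share of 30.9%, which was 14.4% with library totals only (median shift to -0.22 from -0.05). DESeq2 called 246 higher and 390 lower, a fit of only this age 677 and 420, and a fit with no filter on low counts 57 and 108. Count and balance depend on single libraries, since 18 rose and 33 fell without control replicate 2, and 32 rose and 25 fell, more higher than lower, without 2 pg replicate 1. The 10 pg and 2 pg lists shared 48 higher genes (0.38 for independent lists, 17 for simulated lists cut at the observed lengths), and part may come from shared controls.

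At 4 hpf, 6 pg raised FOXC1 by 6.51 ± 0.95 log2 units (adjusted p = 3.61e-05), FGF4 by 6.25 ± 1.14, CYP27C1 by 6.21 ± 0.97, FGF8 by 5.20 ± 0.81 and FLRT3, a cell adhesion protein, by 4.90 ± 0.80. lft1 rose by 3.66 ± 0.61 and lft2 by 3.66 ± 0.54. The AMP deaminase gene AMPD1 fell by 3.31 ± 0.54 (adjusted p = 0.00012) and mt-atp8, a mitochondrial ATP synthase subunit, by 2.79 ± 0.39 (adjusted p = 1.47e-05). Mitochondrial genes held 1.3, 1.61 and 1.46% of the counts in the 3 libraries with 6 pg at 4 hpf, against 4.31, 2.41 and 5.57% in the controls. Among the 5 Nodal ligands and antagonists, 3 rose and 2 were not called (3 adjusted over the list alone, list adjusted p = 0.00861, against adjusted p = 0.206 with an estimated correlation). Of 16 Fgf genes, 8 rose and 8 were not called (9 higher and 1 lower adjusted over the list alone, list adjusted p = 1.96e-05, against adjusted p = 0.206 with an estimated correlation). The 24 enveloping layer, 16 epidermal and 23 early zygotic genes were higher as lists with 4, 5 and 6 members called higher and 0, 1 and 0 lower (adjusted p = 0.0237, 0.00319 and 0.000629, against adjusted p = 0.682, 0.49 and 0.472 with an estimated correlation). In all, 1778 genes rose and 1528 fell. DESeq2 called 2267 and 1946, and a fit of only this age 1008 and 817, and 857 rose and 770 fell without control replicate 1. With the age position defined below as a covariate, 1648 rose and 1422 fell, and 964 of the 1778 stayed higher.

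The 2 pg group at 4 hpf had more calls, and mitochondrial genes held 1.91, 1.56 and 1.45% of its counts. gna15.1, a G protein subunit, rose by 5.09 ± 0.73 (adjusted p = 7.51e-06), the adhesion gene alcamb by 4.96 ± 0.87 and CYP27C1 by 4.92 ± 0.96. ENPEP, a membrane peptidase, fell by 6.02 ± 1.70 (adjusted p = 0.00814), and kitlga, a Kit ligand, by 4.21 ± 0.76. None of the 5 Nodal ligands and antagonists was called, while 1 of 12 endoderm genes, foxa3, rose by 2.88 ± 0.78. Of 24 enveloping layer genes, 13 rose and 11 were not called, with the keratin krt4 at 3.83 ± 0.69 and evpla at 5.51 ± 1.27 (13 higher and 1 lower adjusted over the list alone, list adjusted p = 2.69e-05, against adjusted p = 0.444 with an estimated correlation). Of 20 maternally loaded transcripts, 12 fell, 1 rose and 7 were not called, with slbp2, an oocyte histone-mRNA binding protein, lower by 2.57 ± 0.44 (1 higher and 12 lower adjusted over the list alone, list adjusted p = 0.0041, against adjusted p = 0.361 with an estimated correlation). Of 31 cell cycle genes, 12 rose and 6 fell, with CCND1 at 2.52 ± 0.44 (13 higher and 6 lower adjusted over the list alone, list adjusted p = 0.13). The 16 epidermal, 23 early zygotic and 26 p53 and stress genes were higher as lists with 9, 9 and 7 members called higher and 1, 0 and 2 lower (adjusted p = 0.00191, 0.00264 and 0.018, against adjusted p = 0.481, 0.509 and 0.356 with an estimated correlation).

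In all, 3160 genes rose and 2959 fell with 2 pg at 4 hpf, a higher share of 51.6%, which was 38.2% with library totals only (median shift to -0.20 from -0.03). DESeq2 called 3706 and 3151, and 2150 rose and 1741 fell without 2 pg replicate 1. Each library was placed along the change of the controls, where 0 is control at 4 hpf and 1 control at 6 hpf, over 12425 genes. At 4 hpf the 2 pg libraries stood at 0.284 ± 0.097, 6 pg at 0.204 ± 0.089, 10 pg at 0.088 ± 0.018 and controls at 0 ± 0.079. With this position as a covariate, chosen after the data were seen, 3891 genes were called for 2 pg, 2126 higher and 1765 lower, of which 2553 (1413 higher and 1140 lower) were among the 6119 called without it. The 6 pg and 2 pg lists shared 1528 higher genes (266.6 for independent lists, 905 for simulated lists cut at the observed lengths) and 1259 lower ones (214.5 and 610), and part of this may come from shared controls. The 10 pg list shared 26 higher genes with 6 pg (2.45 for independent lists, 22 simulated at the observed lengths) and 13 with 2 pg (4.35 and 23). Simulated lists this long hold noise shared through the controls, so they do not measure chance sharing of the observed lists.

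**Figure D3:**
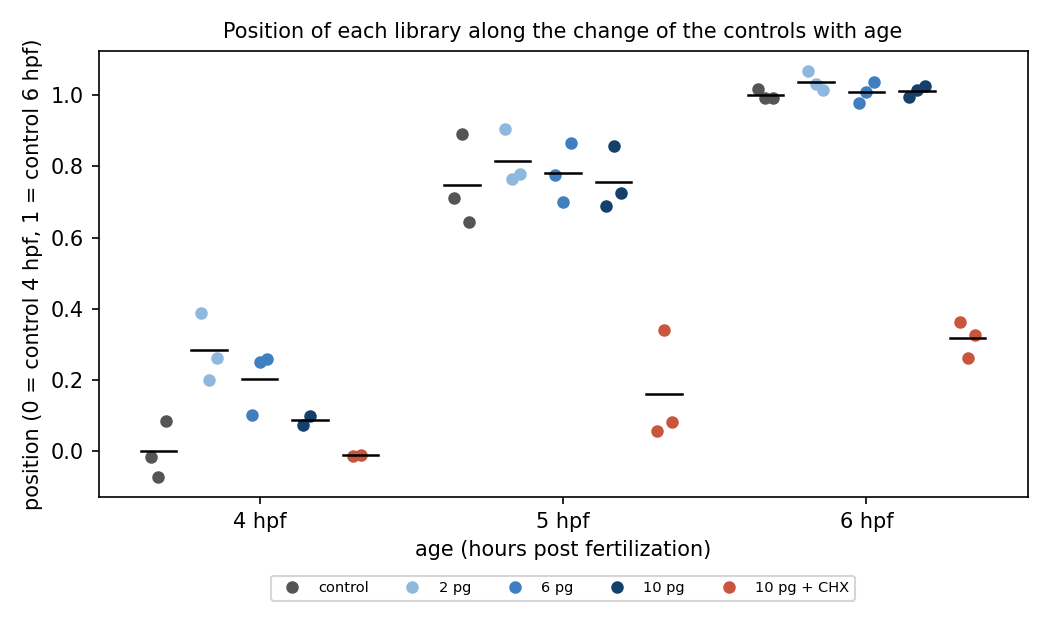
Position of each of the 43 libraries along the change of the controls with age (0 is the mean of control at 4 hpf, 1 that of control at 6 hpf), with group means as bars. At 4 hpf the 2 pg and 6 pg means stand at 0.284 and 0.204, and the CHX means reach 0.161 at 5 hpf and 0.318 at 6 hpf.

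Tested directly, 10 pg exceeded 2 pg at 4 hpf for lft2, by 5.66 ± 0.60 log2 units (adjusted p = 1.28e-07), lft1 by 5.26 ± 0.67 (adjusted p = 1.45e-06), FGF4 by 5.48 ± 1.04 and FGF3 by 5.29 ± 0.85. Of the 5 Nodal ligands and antagonists, 3 were higher and 2 not called (3 adjusted over the list alone, list adjusted p = 9.4e-05). Of 12 endoderm genes, 7 were higher and 5 not called, with sox32 at 4.34 ± 1.08 (7 adjusted over the list alone, list adjusted p = 0.00308, against adjusted p = 0.338 with an estimated correlation). The 20 maternally loaded genes were higher as a list with 7 members called higher and 1 lower (adjusted p = 0.0147, against adjusted p = 0.447 with an estimated correlation). In all, 2227 genes were higher and 2506 lower, a higher share of 47.1%, which was 58.7% with library totals only (median shift to 0.10 from -0.03). The count depends on 10 pg replicate 2. Age positions were 0.284 with 2 pg and 0.088 with 10 pg, so stage as well as dose may enter these calls and lists.

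At 5 hpf, 10 pg exceeded 2 pg for dkk1b by a ratio of 369 (95% counting interval 126 to 1790), GATA5 by 5.53 ± 1.09 log2 units (adjusted p = 0.021), OSR1 by 5.14 ± 0.95 (adjusted p = 0.011), lft1 by 4.60 ± 0.66 (adjusted p = 0.000551) and GSC by 4.34 ± 0.69 (adjusted p = 0.00272). RPL38, a ribosomal protein gene, was lower by 1.2 ± 0.24 (adjusted p = 0.0235). Of 5 Nodal ligands and antagonists, 3 were higher (4 adjusted over the list alone, list adjusted p = 1.88e-10). Lower as lists, with 0 members called, were the 24 enveloping layer and 31 cell cycle genes (adjusted p = 6.04e-07 and 0.0411, against adjusted p = 0.342 and 0.49 with an estimated correlation). The 26 p53 and stress genes were higher as a list with 0 members called (adjusted p = 0.000871, against adjusted p = 0.184 with an estimated correlation). In all, 16 genes were higher and 2 lower, DESeq2 called 56 and 16, and a fit of only this age called 0. The age position as a covariate gave 34 and 4, and 3 were higher and 0 lower without 2 pg replicate 1. Library totals moved the median change to 0.18 from 0.01 at 5 hpf and to 0.15 from 0.04 at 6 hpf. At 6 hpf 5 genes were higher and 0 lower. The forkhead gene foxa stood at 52.5 ± 13.0 against 11.1 ± 2.1 CPM (log2 2.25 ± 0.37, adjusted p = 0.012), the nuclear envelope gene syne3 was higher by 1.1 ± 0.21 (adjusted p = 0.041) and P4HB, a protein disulfide isomerase, by 0.89 ± 0.17 (adjusted p = 0.041). By edgeR 1157 were higher and 414 lower at an unadjusted p below 0.05, DESeq2 called 50 and 4, a fit of only this age 30 and 11, and the fit of all 45 columns as designed 0. Other settings gave 2 with no filter, 8 with library totals, 27 with the age position and 3 without the 2 pg and 6 pg libraries of 4 hpf. Each library left out moved the count, to 0 without 2 pg replicate 1 or 2 and up to 16 without 10 pg replicate 3. Endoderm genes were higher as a list (adjusted p = 1.09e-08) with 0 of 12 called and 5 adjusted over the list alone. The 16 epidermal and 31 cell cycle genes were lower as lists with 0 members called (adjusted p = 4.06e-05 and 0.0437, against adjusted p = 0.338 and 0.492 with an estimated correlation). The 16 yolk syncytial layer and 26 p53 and stress genes were higher as lists with 0 members called (adjusted p = 0.007 and 0.018, against adjusted p = 0.0409 and 0.356 with an estimated correlation).

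With CHX at 4 hpf (n = 2 against 3), sox32 rose from 0.125 ± 0.11 CPM in controls to 36.5 ± 6.22 (log2 8.19 ± 1.17, adjusted p = 0.000156). FOXA2 rose by 6.57 ± 0.94 (adjusted p = 0.000156), FOXC1 by 6.51 ± 0.98, fgf24 by 6.00 ± 0.80 (adjusted p = 3.14e-05) and lft2 by 5.83 ± 0.61 (adjusted p = 2.09e-07). tbxta rose by 5.03 ± 0.93 and GSC by 3.38 ± 0.67. The linker histone gene histh1l1 fell by 4.82 ± 0.62 (adjusted p = 3.14e-05), the enveloping layer gene lye by 4.29 ± 0.85 and STRADA, a kinase adaptor, by 2.13 ± 0.22 (adjusted p = 1.94e-07). Among 12 endoderm genes, 5 rose and 7 were not called (5 adjusted over the list alone, list adjusted p = 1.67e-14). Among the 5 Nodal ligands and antagonists, 3 rose and 2 were not called (3 higher and 1 lower adjusted over the list alone, list adjusted p = 1.83e-09). Among 16 Fgf genes, 4 rose and 12 were not called (4 adjusted over the list alone, list adjusted p = 1.13e-09, against adjusted p = 0.0576 with an estimated correlation). As a list the 24 enveloping layer genes were lower with 1 member called lower (adjusted p = 1.36e-05, against adjusted p = 0.414 with an estimated correlation). The 16 yolk syncytial layer and 31 cell cycle genes were higher as lists with 1 and 0 members called higher (adjusted p = 0.0437 and 0.0446, against adjusted p = 0.14 and 0.493 with an estimated correlation). In all, 33 genes rose and 20 fell, and DESeq2 called 87 and 103. With the shared column given to the CHX group alone, an assignment tried after the data were seen, 94 rose and 86 fell. The age position as a covariate gave 78 and 82. The balance turned without CHX replicate 1 (35 rose and 110 fell) and without control replicate 2 (23 and 35), while 19 rose and 13 fell without control replicate 1.

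Against 10 pg alone at 4 hpf (n = 2 each), krt92, a keratin, had 0 counts with CHX and was at least 70.9-fold lower, krt4 was lower by 6.00 ± 1.00 log2 units (adjusted p = 0.00326), lye by 6.00 ± 0.91 (adjusted p = 0.00102) and the claudin cldnb by 4.85 ± 1.02. Of 24 enveloping layer genes, 6 were lower and 18 not called (8 adjusted over the list alone, list adjusted p = 9.81e-13, against adjusted p = 0.151 with an estimated correlation). Of 26 p53 and stress genes, 2 were lower, PHLDA3 by 3.78 ± 0.83 and XBP1 by 1.42 ± 0.32 (5 adjusted over the list alone, list adjusted p = 5.36e-05, against adjusted p = 0.0919 with an estimated correlation). The 16 epidermal and 23 early zygotic genes were lower as lists with 3 and 1 members called lower (adjusted p = 1.19e-05 and 0.00135, against adjusted p = 0.3 and 0.49 with an estimated correlation). sp5l, a Wnt-responsive zinc finger gene, was higher by 4.45 ± 0.92 (adjusted p = 0.0194) and the demethylase gene kdm4ab by 2.06 ± 0.39. In all, 40 genes were higher and 77 lower. This count depends on the identical column. All 45 columns as designed gave 0 and 7, the column in 10 pg alone 0 and 0, and in CHX alone 272 and 290. A fit of only this age gave 0 and 8, replicate numbers as a block 29 and 62, a block within each age 20 and 41, no filter 23 and 54, and DESeq2 162 and 265. It depends on single libraries too, with 0 and 2 without CHX replicate 1, 0 and 9 without 10 pg replicate 2, and the balance turned without 10 pg replicate 1 (195 and 129) and CHX replicate 2 (47 and 34).

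With CHX at 5 hpf (n = 3 each), SOX17, an endoderm factor, rose by 7.40 ± 1.53 log2 units (adjusted p = 0.000196) and sox32 by 7 ± 1.18 (adjusted p = 9.97e-06). The growth factor VEGFC rose by 6.63 ± 1.26, OSR1 by 5.89 ± 1.06, tbxta by 5.30 ± 0.92 (adjusted p = 1.74e-05), lft2 by 4.90 ± 0.68 (adjusted p = 4.31e-07) and lft1 by 3.23 ± 0.65. krt92 fell from 719 ± 656 to 0.0609 ± 0.0225 CPM (adjusted p = 2.37e-10), and krt17 and tmsb1 fell by ratios of 6930 (95% counting interval 1240 to 274000) and 2980 (826 to 24700). Of 24 enveloping layer genes, 24 fell (24 adjusted over the list alone, list adjusted p = 6.81e-17, against adjusted p = 0.0823 with an estimated correlation). Of 16 epidermal genes, 11 fell and 5 were not called, with krt8 lower by 9.09 ± 0.75 (11 adjusted over the list alone, list adjusted p = 2.69e-05, against adjusted p = 0.33 with an estimated correlation). Of the 12 endoderm genes, 9 rose, 1 fell and 2 were not called (9 and 1 adjusted over the list alone, list adjusted p = 0.00298, against adjusted p = 0.338 with an estimated correlation).

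Of 20 maternally loaded transcripts, 13 rose with CHX at 5 hpf, 3 fell and 4 were not called, with the oocyte growth factor bmp15 at 3.93 ± 0.51 and the germ plasm organizer buc at 3.91 ± 0.57 (13 and 3 adjusted over the list alone, list adjusted p = 0.00058, against adjusted p = 0.26 with an estimated correlation). With the age position as a covariate, buc was no longer called and its estimate turned negative. Of 14 primordial germ cell genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone, list adjusted p = 0.0315, against adjusted p = 0.487 with an estimated correlation). Of 23 early zygotic genes, 17 fell and 2 rose, with the polymerase subunit gene polr3gla lower by 7.41 ± 0.65 (18 and 2 adjusted over the list alone, list adjusted p = 4.95e-06, against adjusted p = 0.321 with an estimated correlation). Of 26 p53 and stress genes, 14 fell and 3 rose, with PHLDA3 lower by 4.67 ± 0.66 (15 and 3 adjusted over the list alone, list adjusted p = 0.00242, against adjusted p = 0.219 with an estimated correlation). Of 31 cell cycle genes, 16 fell and 6 rose, with MCM3 lower by 4.14 ± 0.66 (16 and 6 adjusted over the list alone, list adjusted p = 0.0324, against adjusted p = 0.481 with an estimated correlation).

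In all, 5089 genes rose and 5194 fell with CHX at 5 hpf, a higher share of 49.5%, which was 67.5% with library totals only (median shift to 0.49 from 0.05), and 4467 rose and 4380 fell without CHX replicate 3. The CHX libraries stood at an age position of 0.161 ± 0.156 at 5 hpf and 0.318 ± 0.05 at 6 hpf, against 0.748 ± 0.127 and 1 ± 0.014 in controls. With that position as a covariate, tried after the data were seen, 511 rose and 358 fell. The position is computed from the same genes, so this setting also takes out any CHX effect along it.

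Against 10 pg alone at 5 hpf, dkk1b was lower with CHX by 7.25 ± 0.96 log2 units (adjusted p = 2.39e-07), sebox by 5.79 ± 0.87, FGF4 by 4.87 ± 0.95, noto by 2.70 ± 0.65, lft1 by 2.12 ± 0.56 (adjusted p = 0.0021) and lft2 by 1.83 ± 0.50 (adjusted p = 0.00256). VEGFC had 0 counts with 10 pg alone and was at least 167-fold higher, and SOX17 was higher by 5.20 ± 1.29 (adjusted p = 0.00134). Of 16 Fgf genes, 12 were lower, 1 higher and 3 not called (12 and 1 adjusted over the list alone, list adjusted p = 0.00185, against adjusted p = 0.385 with an estimated correlation). The 24 enveloping layer and 16 epidermal genes were lower as lists with 24 and 10 members called lower (adjusted p = 7.08e-16 and 0.000127, against adjusted p = 0.0919 and 0.378 with an estimated correlation). The 23 early zygotic and 26 p53 and stress genes were lower as lists with 18 and 18 members called lower and 1 and 3 higher (adjusted p = 9.37e-07 and 0.000453, against adjusted p = 0.273 and 0.151 with an estimated correlation). The 14 primordial germ cell and 20 maternally loaded genes were higher as lists with 8 and 13 members called higher and 2 and 3 lower (adjusted p = 0.0244 and 0.000382, against adjusted p = 0.472 and 0.24 with an estimated correlation). In all, 5265 genes were higher and 5108 lower, a higher share of 50.8%, which was 64.1% with library totals only (median shift to 0.36 from 0.03), and 5270 were higher and 5465 lower without CHX replicate 2. With the age position as a covariate 353 were higher and 223 lower.

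With CHX at 6 hpf (n = 3 each), sox32 rose by 7.60 ± 1.19 log2 units (adjusted p = 2.68e-06), GSC by 6.37 ± 0.77 (adjusted p = 4.22e-08), tbxta by 6.53 ± 0.97 (adjusted p = 1.29e-06), lft1 by 4.82 ± 0.74 and lft2 by 4.05 ± 0.66. SOX17 rose by a ratio of 907 (95% counting interval 162 to 35800), and EN2, a midbrain homeobox gene with 0 counts in controls, at least 130-fold. EN2 (ENSDARG00000026599) shares its symbol with another gene, so the paralog is uncertain. krt92 fell by a ratio of 108000 (19500 to 4280000), and the cell adhesion receptor cd44a, with 0 counts with CHX, at least 1560-fold. Of the 5 Nodal ligands and antagonists, 5 rose, with ndr1 at 4.88 ± 0.65 (5 adjusted over the list alone, list adjusted p = 0.00317, against adjusted p = 0.15 with an estimated correlation). Of 12 endoderm genes, 10 rose, 1 fell and 1 was not called (10 and 1 adjusted over the list alone, list adjusted p = 0.000227, against adjusted p = 0.212 with an estimated correlation). Of 24 enveloping layer genes, 22 fell and 2 were not called (22 adjusted over the list alone, list adjusted p = 6.22e-16, against adjusted p = 0.0919 with an estimated correlation). Of 20 maternally loaded transcripts, 16 rose and 2 fell, with BTG4, a deadenylation adaptor, at 5.08 ± 0.58 (16 and 2 adjusted over the list alone, list adjusted p = 6.33e-05, against adjusted p = 0.188 with an estimated correlation). The 16 epidermal and 23 early zygotic genes were lower as lists with 11 and 13 members called lower and 1 and 3 higher (adjusted p = 0.000152 and 0.00314, against adjusted p = 0.385 and 0.523 with an estimated correlation). The 14 primordial germ cell genes were higher as a list with 9 members called higher and 1 lower (adjusted p = 0.00532, against adjusted p = 0.361 with an estimated correlation). Of 16 neural ectoderm genes, 6 rose and 7 fell (6 and 7 adjusted over the list alone, list adjusted p = 0.799), with a median of 0.14, a mean of -0.02 and a test direction of lower.

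In all, 5978 genes rose and 5563 fell with CHX at 6 hpf, a higher share of 51.8%, which was 69.5% with library totals only (median shift to 0.61 from 0.10). With the age position as a covariate 804 rose and 528 fell. Against 10 pg alone at 6 hpf, dkk1b was lower by 6.44 ± 0.89 log2 units (adjusted p = 2.95e-07), pcdh8 by 5.80 ± 0.82 (adjusted p = 5.82e-07), sebox by 5.22 ± 0.84, FOXA2 by 4.02 ± 0.76, lft2 by 2.96 ± 0.52 and lft1 by 2.1 ± 0.56. The retinal homeobox gene rx3 was higher by 7.51 ± 1.03 (adjusted p = 3.4e-07) and the hormone gene CRH by 5.60 ± 1.08. Of 21 ventrolateral and paraxial mesoderm genes, 12 were lower, 1 higher and 8 not called (12 and 1 adjusted over the list alone, list adjusted p = 0.00407, against adjusted p = 0.266 with an estimated correlation). The 24 enveloping layer and 16 epidermal genes were lower as lists with 22 and 10 members called lower and 0 and 1 higher (adjusted p = 1.34e-15 and 0.000907, against adjusted p = 0.0954 and 0.451 with an estimated correlation). The 23 early zygotic and 26 p53 and stress genes were lower as lists with 15 and 11 members called lower and 1 and 3 higher (adjusted p = 0.000547 and 0.031, against adjusted p = 0.468 and 0.405 with an estimated correlation). The 14 primordial germ cell and 20 maternally loaded genes were higher as lists with 8 and 16 members called higher and 1 and 2 lower (adjusted p = 0.00451 and 7.83e-05, against adjusted p = 0.353 and 0.194 with an estimated correlation). Here 6120 genes were higher and 5726 lower, a higher share of 51.7%, which was 70% with library totals only (median shift to 0.68 from 0.12). With the age position as a covariate 686 were higher and 502 lower.

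Genes higher than control both with 10 pg alone and with 10 pg and CHX numbered 19 at 4 hpf (12 without control replicate 2), 32 at 5 hpf and 64 at 6 hpf. At 4 hpf FOXA2 rose by 6.80 and 6.57 log2 units in the 2 comparisons, FOXC1 by 7.58 and 6.51, FGF3 by 6.53 and 5.95, lft2 by 5.65 and 5.83 and lft1 by 5.61 and 5.46. At 5 hpf OSR1 rose by 7.23 and 5.89, tbxta by 6.32 and 5.30, lft2 by 6.74 and 4.90, GATA5 by 5.39 and 4.38 and GATA6 by 4.33 and 4.29. At 6 hpf sox32 rose by 6.56 and 7.60, tbxta by 7.31 and 6.53, GSC by 6.81 and 6.37, foxa3 by 7.29 and 6.13 and IRX3 by 6.21 and 6.89. SHH, the Hedgehog ligand, had 0 counts in controls at 6 hpf and rose at least 62.2-fold and at least 34.4-fold. SHH (ENSDARG00000038867) shares its symbol with another gene, so the paralog is uncertain.

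Independent lists would share 0.05, 11.4 and 28.4 genes at 4, 5 and 6 hpf. Lists cut at the observed lengths in data simulated without an effect on the same controls shared 5, 40 and 88. The 32 and 64 genes at 5 and 6 hpf are below those numbers, which do not measure chance there. The simulated CHX lists hold only noise, shared with 10 pg through the controls. The observed ones hold 5089 and 5978 genes called higher with CHX. Both comparisons use the same 3 controls, so part of the sharing may come from them. At 5 hpf 7 genes were shared with only the libraries of that age in the fit. At 4 hpf 13 were shared with replicate numbers as a block within each age, and 7 of the 19 were among them. A gene outside the shared set is not thereby shown to respond differently with CHX.

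**Figure D4:**
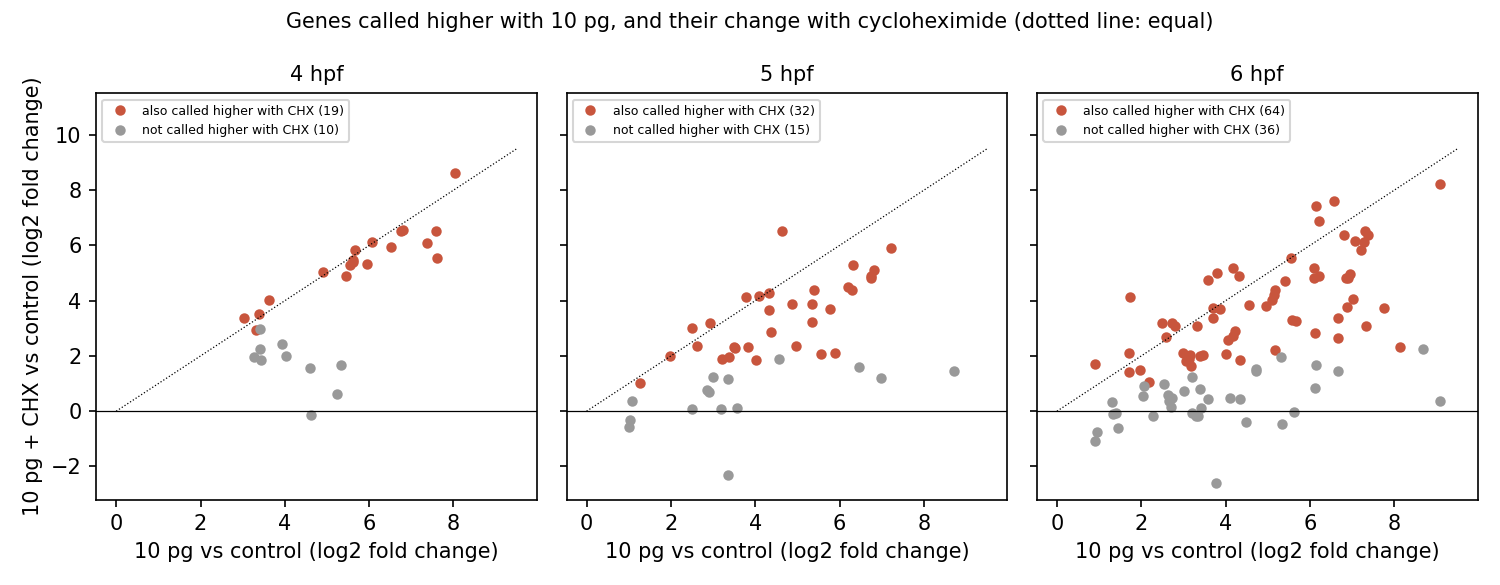
Log2 fold change against control with 10 pg (horizontal) and with 10 pg and CHX (vertical) for the 29, 47 and 100 genes higher with 10 pg at 4, 5 and 6 hpf, as fitted, also where a group held few counts. Coloured points mark the 19, 32 and 64 genes also called higher with CHX, and the dotted line marks equal change.

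In uninjected controls evpla, a cornified envelope protein, rose from 4 to 5 hpf by 11.78 ± 1.28 log2 units (adjusted p = 1.1e-08), krt5 from 1.12 ± 1.29 to 1813 ± 2150 CPM (adjusted p = 1.63e-08), and the disulfide isomerase agr1, with 0 counts at 4 hpf, at least 321-fold. The Bmp feedback inhibitor szl rose by 10.60 ± 1.78 (adjusted p = 9.56e-06). buc fell from 450 ± 151 to 21.0 ± 9.31 CPM (adjusted p = 2.34e-07), slbp2 by 4.43 ± 0.49 and the potassium channel gene kcnn1b by 6.82 ± 1.33. Of 24 enveloping layer genes, 23 rose and 1 was not called (23 adjusted over the list alone, list adjusted p = 9.71e-13, against adjusted p = 0.151 with an estimated correlation). Of 20 maternally loaded transcripts, 15 fell, 2 rose and 3 were not called (15 and 2 adjusted over the list alone, list adjusted p = 5.76e-05, against adjusted p = 0.188 with an estimated correlation). Of 23 early zygotic genes, 16 rose and 1 fell, with the homeobox repressors ved at 5.29 ± 0.83 and vox at 4.38 ± 0.44 (16 and 1 adjusted over the list alone, list adjusted p = 1.73e-05, against adjusted p = 0.347 with an estimated correlation). Of 20 Bmp genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone, list adjusted p = 0.0314, against adjusted p = 0.49 with an estimated correlation). The 16 epidermal, 26 p53 and stress and 31 cell cycle genes were higher as lists with 14, 16 and 18 members called higher and 1, 3 and 5 lower (adjusted p = 5.09e-05, 0.00331 and 0.0289, against adjusted p = 0.342, 0.24 and 0.472 with an estimated correlation). The 14 primordial germ cell genes were lower as a list with 10 members called lower and 4 higher (adjusted p = 0.034, against adjusted p = 0.49 with an estimated correlation).

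In all, 5981 genes rose and 5426 fell from 4 to 5 hpf in controls, a higher share of 52.4%, which was 35.9% with library totals only (median shift to -0.41 from 0.03). From 5 to 6 hpf, 288 rose and 1426 fell, and DESeq2 called 756 and 1759. Each of the 6 libraries, left out, moved this count by over 1.5 times, from 33 higher and 562 lower without replicate 1 of 5 hpf, or 61 and 507 without replicate 1 of 6 hpf, to 1480 and 2273 without replicate 2 of 5 hpf. PKDCC, a secreted kinase, rose by 4.23 ± 0.95 (adjusted p = 0.00593) and the RNA-binding gene RBM47 by 3.06 ± 0.74. The Hairy-related factor her5 fell by 3.18 ± 0.66 (adjusted p = 0.00332). Of 20 maternally loaded transcripts, 9 fell, 0 rose and 11 were not called, with BTG4 lower by 2.27 ± 0.53 and buc by 2.00 ± 0.55 (9 adjusted over the list alone, list adjusted p = 0.000137, against adjusted p = 0.206 with an estimated correlation). The 24 enveloping layer, 16 epidermal and 16 neural ectoderm genes were higher as lists with 0 members called higher and 0, 0 and 1 lower (adjusted p = 2.99e-05, 0.019 and 0.011, against adjusted p = 0.444, 0.583 and 0.323 with an estimated correlation). The 14 primordial germ cell genes were lower as a list with 2 members called lower (adjusted p = 0.00308, against adjusted p = 0.338 with an estimated correlation).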

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

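The linear age trend tests and their bounds, the library scaling test and all counts of splits were chosen after the results were seen, and the other tests below were written after age positions and call counts had been seen.

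At 4 hpf the 2 pg and 6 pg groups gave 6119 and 3306 calls where 10 pg gave 31. Of the calls, 90.1% for 2 pg and 90.3% for 6 pg had the sign of the change of the 10 pg group from 4 to 5 hpf, in which 51.8% of all genes rise, so somewhat later sampling or faster development of these libraries is a candidate explanation. A linear age trend as the whole cause was not settled. With the age position as a covariate 41.7% of the 6119 calls (2553) stayed called in the same direction, close to the bound of 40%. In all 63.6% as many were made, 3891 for 2 pg, new ones included. The median change of the 6119 went to 0.96 from 1.29 (median standard error 0.37 from 0.32). Each group kept its own mean in that fit, so the age slope rests on the spread within groups. It may be too small for the gap between groups, and an age trend is not excluded. For the genes called with 2 pg, a response that grows with dose was argued against, since the median change of 10 pg in the direction of the 2 pg calls was 0.09 against 1.29 for 2 pg. The genes called with 6 pg were not tested this way. Of the 1778 higher ones, 26 were among the 29 higher with 10 pg. Batch or clutch differences were not testable, because the labels do not name them.

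The calls of CHX against control at 5 and 6 hpf went back along normal development. At 6 hpf 86.5% of them had the sign opposite to the control change from 4 to 5 hpf (86% of those at 5 hpf against the 10 pg change from 4 to 6 hpf), so explants held near the 4 hpf state may account for much of the count. A state held exactly at 4 hpf as the whole cause was argued against, since CHX at 5 hpf still differed from control at 4 hpf in 4584 genes (10283 against control at 5 hpf). One scaling factor for the CHX libraries as the whole cause was argued against, since it would move every gene alike, and over log2 shifts of -3 to 3 the fewest calls were 99.3% of those at 6 hpf (11460, with 4899 above and 6561 below the shift) and 100% of those at 5 hpf. How many rose or fell depends on the scaling (8369 and 3671 at 6 hpf with library totals, 5978 and 5563 with TMM) and stays open, as does what CHX does without ndr2, and with the age position as a covariate 869 calls were made at 5 hpf and 1332 at 6 hpf.

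With 2 pg at 6 hpf, 92% of the 262 calls had the sign of the 10 pg change from 5 to 6 hpf, in which 47.7% of all genes rise. A later stage is a candidate, but the ndr2 response may enter that change too, so for genes called higher it cannot tell them apart. With the age covariate all 262 stayed called in the same direction, of 386. This cannot decide on a linear age trend, since 2 pg stood at 1.036 ± 0.027 and controls at 1 ± 0.014. The covariate thus had little to remove, and the median change went to 1.30 from 1.37 (median standard error 0.29 from 0.31). An age difference, along that line or not, stays open. For genes called lower, a response that grows with dose was argued against by a 10 pg median of 0.34 against 1.2 for 2 pg. For genes called higher, the 10 pg median of 3.3 against 2.48 goes with such a response. The 2 explanations may each hold for part of the calls, and injection batch stays open.

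The effect of 10 pg at 6 hpf minus that at 4 hpf was 9.43 for dkk1b, 8.40 as fitted for TBR1 (2 counts over the controls at 6 hpf, so no measured size), 6.79 for lhx1a, 6.65 for IRX3, 4.33 for SULF1, 4.28 for NRIP1, 2.34 for arhgef37, 2.22 for RASGEF1B, 1.91 for SCUBE2 and -4.26 for TAGLN. No cause of these differences was tested. The 4 hpf side rests on 2 libraries, so splits of the samples were not counted for it.

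The identical column of the 10 pg and CHX groups at 4 hpf, left out of the comparisons, held 51.7 CPM of ndr2. Its group was not inferred from its values.

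Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For 10 pg against control, 2 of the 10 splits at 5 hpf gave as many calls (47, highest other 94), and 1 at 6 hpf, the real one (100, highest other 0). For 6 pg it was 1 at 4 hpf (3306, highest other 150), 2 at 5 hpf (37, highest other 944) and 1 at 6 hpf (134, highest other 0). For 2 pg it was 1 at each age (6119, highest other 269, then 1, highest other 0, and 262, highest other 0). For 10 pg against 2 pg it was 1 at 5 hpf (18, highest other 3) and 1 at 6 hpf (5, highest other 0).

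For CHX against control it was 1 of 10 at 5 hpf (10283, highest other 3605) and at 6 hpf (11541, highest other 0), and for CHX against 10 pg 1 of 10 at 5 hpf (10373, highest other 1418) and at 6 hpf (11846, highest other 0). For the controls it was 1 from 4 to 5 hpf (11407, highest other 753) and 1 from 5 to 6 hpf (1714, highest other 46). Where replicate numbers pair the libraries, the splits that part as many pairs gave at most 0 calls for 10 pg at 6 hpf, 882 for CHX against control at 5 hpf, 0 at 6 hpf and 0 for CHX against 10 pg at 5 hpf. Of 100 splits, 14 gave as many genes higher in both 10 pg and CHX at 5 hpf (32, highest other 4289), and 4 at 6 hpf (64, highest other 5218). These splits deal the control, 10 pg and CHX libraries over all the groups, so the CHX effect itself enters their counts. They cannot tell chance from that effect, and chance is not excluded at either age.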

How the results depend on the processing

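The age position as a covariate, the block within each age, the settings of the shared column, the fits without the 2 pg and 6 pg libraries of 4 hpf and library totals outside the CHX results were chosen after the results were seen. Of 3540 gene values over all settings, 342 were weaker or no longer called and 1 turned. By gene, 117 of 225 named gene comparisons were kept in every setting, 107 were weaker or no longer called in at least 1 setting and 1 turned. buc with CHX against control at 5 hpf went to -0.55 from 3.91 with the age position as a covariate (adjusted p = 0.695 there). RLE scaling and the replicate block moved 0 of 24 counts by over 1.5 times. As a block, replicate numbers ended 3 and added 1 of 196 list calls over 21 comparisons, none in the 4 comparisons that pair, where no gene count moved by over 1.5 times.

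Totals of calls moved as follows, and a total that did not move can still hold other genes. For 10 pg against control DESeq2 gave 86 at 4 hpf (31 with edgeR) and libraries of the same age 9 at 5 hpf (47). For 6 pg, libraries of the same age gave 1825 at 4 hpf (3306), 3 at 5 hpf (37) and 289 at 6 hpf (134), DESeq2 gave 61 at 5 hpf and 222 at 6 hpf, and the age covariate 202 at 6 hpf. For 2 pg the age covariate gave 3891 at 4 hpf (6119). At 5 hpf (1) all 45 columns and libraries of the same age gave 0 and DESeq2 14. At 6 hpf (262) no filter gave 165, library totals 493, libraries of the same age 1097 and DESeq2 636.

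For 10 pg against 2 pg at 5 hpf (18) the age covariate gave 38, libraries of the same age 0 and DESeq2 72. At 6 hpf (5) no filter gave 2, library totals 8, all 45 columns 0, the age covariate 27, leaving out 2 pg and 6 pg at 4 hpf 3, libraries of the same age 41 and DESeq2 54. For CHX against control the shared column only in CHX gave 180 at 4 hpf (53), the age covariate 160 and DESeq2 190, and the age covariate gave 869 at 5 hpf and 1332 at 6 hpf. For CHX against 10 pg at 4 hpf (117) no filter gave 77, all 45 columns 7, the shared column only in 10 pg 0, only in CHX 562, the block within each age 61, libraries of the same age 8 and DESeq2 427. The age covariate gave 576 at 5 hpf and 1188 at 6 hpf. For the 10 pg effect at 6 against 4 hpf (10) library totals gave 6, the block within each age 18 and DESeq2 26. Genes higher in both at 5 hpf (32) were 7 with libraries of the same age. The cause of these shifts was not tested.

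Leaving out 1 library moved 59 of 151 counts by over 1.5 times. Where it left 1 library in a group, that lone sample was assumed to vary like the other groups. For 10 pg against control the range was 18 (without control replicate 2) to 585 (without 10 pg replicate 1) at 4 hpf, 30 (control 2) to 87 (control 3) at 5 hpf and 64 (control 2) to 91 (10 pg 1) at 6 hpf. For 6 pg it was 1627 (control 1) to 3318 (control 3), 19 (control 1) to 46 (6 pg 2) and 76 (control 3) to 140 (6 pg 1). For 2 pg it was 3891 (2 pg 1) to 6216 (2 pg 2), 0 (control 1) to 1 (2 pg 2) and 51 (control 2) to 237 (2 pg 3).

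For 10 pg against 2 pg it was 1217 (10 pg 2) to 4760 (2 pg 2) at 4 hpf, 3 (2 pg 1) to 18 (10 pg 3) at 5 hpf and 0 (2 pg 1) to 16 (10 pg 3) at 6 hpf. For CHX against control it was 32 (control 1) to 145 (CHX 1), 8691 (CHX 1) to 10530 (CHX 2) and 10179 (CHX 2) to 10593 (CHX 1). For CHX against 10 pg it was 2 (CHX 1) to 324 (10 pg 1), 8630 (CHX 1) to 10735 (CHX 2) and 10618 (CHX 2) to 11072 (10 pg 1). For controls it was 9806 (4 hpf 2) to 11086 (4 hpf 3), and from 5 to 6 hpf 568 (6 hpf 1) to 3753 (5 hpf 2). The 10 pg effect at 6 against 4 hpf gave 0 (10 pg 2 at 4 hpf) to 43 (10 pg 1 at 4 hpf). Genes higher in both gave 12 to 20, 23 to 46 and 45 to 63 at 4, 5 and 6 hpf.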

Other observations

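At 5 hpf SOX17 and VEGFC stood higher with CHX than with 10 pg alone, while dkk1b, sebox and FGF4 stood lower. FGF4 was still called higher than control with CHX at 4 hpf (log2 5.53, adjusted p = 0.0252) and at 6 hpf (log2 3.1, adjusted p = 0.0332), and not at 5 hpf (log2 1.59, adjusted p = 0.198). ndr2 itself was 1.89 log2 units higher with CHX than with 10 pg alone at 5 hpf. A CHX group without ndr2 was not analysed here, the counts do not tell synthesis from decay, and no cause of these differences was tested.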
